A study of Mus musculus with 12 samples.

How the data were processed

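Heart RNA of 12 mouse libraries in 4 groups of 3 was measured by RNA sequencing. A single table of 19246 genes was used. The estimated counts per gene and library were deposited by the authors, and between 19.7% and 22.8% of the values in a library are fractional (more than 0.005 from a whole number). The second set of values in the table was taken as FPKM: per the file headers it is only an expression value, and for the 1097 genes above 50 in every library the gene length implied by count, value and library total varied by a median of 0.457% between libraries. The genome build was mm10, per the submitters' processing notes; the aligner, the counting tool and the annotation are not given in the sources used here. The authors' group means of the estimated counts and of FPKM are also in the table (8 columns) and were not used. No value column of the table lacked a match to a library or group.

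Groups and replicate numbers were taken from the sample titles. The group codes in the titles are longer than those the series design text explains and were read as the same 4 groups, HBA0 as its B0 (busulfan alone). The tissue label of the samples reads Cells, while the extraction protocol and the series title name the heart, and the samples were taken as heart. A gene has a symbol and either a numeric Entrez identifier (18268 genes) or an identifier of an unnamed gene model (978 genes). Coordinates are those of the RefSeq annotation of GRCm38, the same assembly as mm10, matched on the Entrez identifier.

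Estimated counts were rounded to whole numbers, which changed a library total by at most 18.1 counts. Genes were filtered with filterByExpr, which kept 14687 genes and left out 4559, and libraries were scaled with TMM factors. All 12 libraries were fitted together with group means in edgeR 4.0.16 (quasi-likelihood test, R 4.3.3), with a Benjamini-Hochberg threshold of 0.05 per comparison. The common biological coefficient of variation was 29.1%. Standard errors of log2 fold changes are the absolute log2 fold change divided by the square root of the F statistic. Comparisons were the 4 pairs of groups, both main effects, the interaction and an F test over the groups. The pair busulfan plus AOS against AOS was added after seeing the data. With 3 libraries against 3, an exact permutation test of a single value cannot go below p = 0.1, so no such p-value is given for pairs. The 10 splits of a pair are given as counts only.

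The design, the gene lists, the rule for named genes and the first set of alternatives below were fixed before the data were examined. Of 39 gene lists, 37 had at least 3 tested genes. They were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with the correlation estimated from the residuals, and with fry. Adjusted p-values are over the 37 lists within a comparison. Named genes followed a rule. For each pair of groups it takes the 10 higher and 10 lower genes with the largest change among those past the threshold, without overlap between groups and with a mean of at least 5 CPM in a group. With fewer than 10 such genes, the genes with the smallest unadjusted p fill the list up to 10, and up to 4 members of each gene list may be named. Main effects and the interaction use 5 in each direction, and overlap was judged on 6 against 6 libraries for main effects and not at all for the interaction. Symbols of predicted genes were left out by the rule. Identifiers of unnamed gene models were left out too, an addition made after seeing the data that removed 1 gene in 5 of the 7 comparisons. Any member of 4 lists that check the tissue or the sex of the samples may be named.

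The test was run on simulated data: counts for the real genes were drawn from the real means, dispersions and library totals, with 200 genes changed. For busulfan against control, run on 14465 genes, 33.5% of genes changed 2-fold were recovered, and on 14458 genes 74.0% of those changed 4-fold. For the main effect of busulfan the shares were 61.5% on 14504 genes and 87.0% on 14482 genes. With no change simulated, 0 genes were called in any comparison. The list test with the preset correlation then called 1 of 37 lists for busulfan plus AOS against busulfan, for busulfan plus AOS against control and for the main effect of AOS, and 0 for the others. Each gene was drawn independently, so the simulated lists had no correlation between genes. In the real data the estimated correlation ranged from -0.0194 (p53 targets) to 0.919 (mesothelium markers) for busulfan against control. The simulated list counts therefore do not carry over to the real lists. The recovered shares have a like limit, since no change shared by the genes of a library was simulated. Unchanged genes called with 2-fold and 4-fold changes numbered 5 and 3 for busulfan against control. For the main effect of busulfan they numbered 6 and 9.

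For genes high in a single library, a gene was taken when it had at least 20 CPM there, at least 30 times the median of the other groups and more than 2 times each other library of its group; these limits were set after seeing the data. The first set of alternatives was scaling by RLE or by library totals, DESeq2 1.42.0, limma-voom without and with library weights, no filter, a filter of 5 CPM in 3 libraries, only the groups compared, a replicate block, each library left out, a threshold of 0.1, other set tests and, for correlations, genes above the median expression. Those meant for a table without counts (pseudocounts, quantile and median-of-ratios scaling, a variance trend) did not apply. Alternatives chosen after seeing the data were a covariate for atrial or adipocyte markers, 2 libraries left out together, subtraction of the estimated share passed between libraries, and limma on log2(FPKM + 1). Regroupings of the 12 libraries were drawn 100 times, the real grouping included.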

Results

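RNA was sequenced from mouse hearts of 4 groups with 3 libraries each. Control mice were untreated. A second group received alginate oligosaccharides (AOS), short sugar chains made from the alginate of brown algae, at 10 mg/kg for 5 weeks. The busulfan group received a single dose of busulfan, a DNA-alkylating drug, at 40 mg/kg, and the last received busulfan and then AOS at the same doses. Library totals lay between 9929772 and 13620815 estimated counts, lowest in control replicate 1 and highest in replicate 1 of busulfan plus AOS. Of 19246 genes in the table, 14687 had enough counts to be tested. The labels do not say whether the libraries of a group came from separate hearts, so p-values measure the spread between libraries. The Y-linked gene Ddx3y lay between 21.3 and 33.0 FPKM in all 12 libraries.

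Transcripts of tissues around the ventricle differed widely between libraries. Myl7, the atrial myosin light chain, ranged from 132 to 3321 FPKM within the control group, from 11.4 to 5565 with AOS, from 6.34 to 1035 with busulfan and from 1177 to 5488 with busulfan plus AOS. Bmp10, an atrial growth factor, was listed at 0 in all control libraries and reached 252 FPKM in AOS replicate 2. The fat hormone gene Adipoq was at 3.19 ± 4.78 FPKM (SD, n = 3) in control hearts and at 102 ± 41.5 (n = 3) after busulfan plus AOS. The airway secretory gene Scgb1a1 reached 4155 FPKM in AOS replicate 2 and 1031 in replicate 1 of busulfan plus AOS, against 45.7 to 85.1 in controls. The liver gene Alb, chosen after its values were seen, reached 871 FPKM in replicate 2 of busulfan plus AOS. The first principal component held 43.9% of the variance between libraries.

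**Figure D1:**
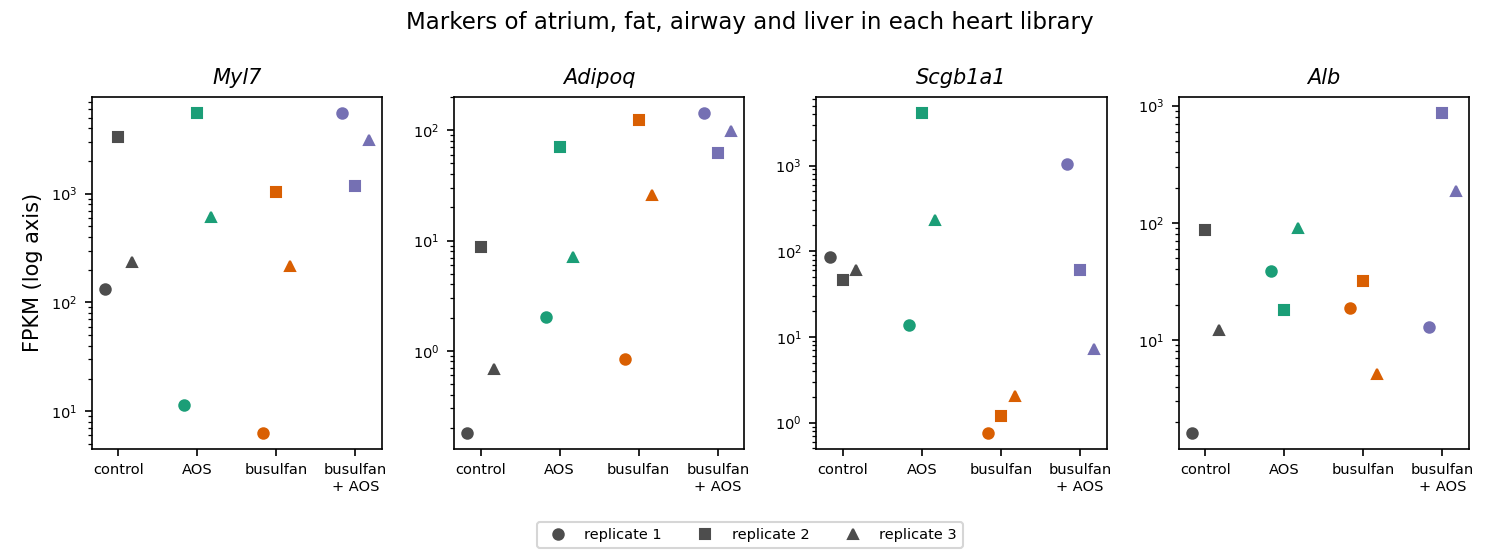
FPKM on a log axis of Myl7 (atrium), Adipoq (fat), Scgb1a1 (airway) and Alb (liver) in the 12 libraries, with 1 symbol per replicate in each of 4 groups. Myl7 spans 6.34 to 5565 FPKM, and the values within a group differ by as much as 489 times.

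Many genes that were high in a single library were also present, at a nearly fixed share, in 1 particular other library of the same group. The airway genes Scgb1a1 and Bpifa1 and the atrial gene Bmp10, high in AOS replicate 2, were found in AOS replicate 3 at 6.52%, 6.29% and 7.15% of that level. In AOS replicate 1 they were at 0.397%, 0.288% and 0.239%. Acadl, an enzyme of fatty acid oxidation, was at 75 FPKM in control replicate 2, and control replicate 3 held 8.56% of its level. The beta-globin gene Hbb-bs was at 1909 FPKM in replicate 3 of busulfan plus AOS, and replicate 1 of that group held 9.52% of its level. Hbb-bs shares sequence with other beta-globin genes, so its count is uncertain. Across the 10 libraries with such genes, the next-numbered library (1 to 2, 2 to 3, 3 to 1) held the higher median share in 9.

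**Figure D2:**
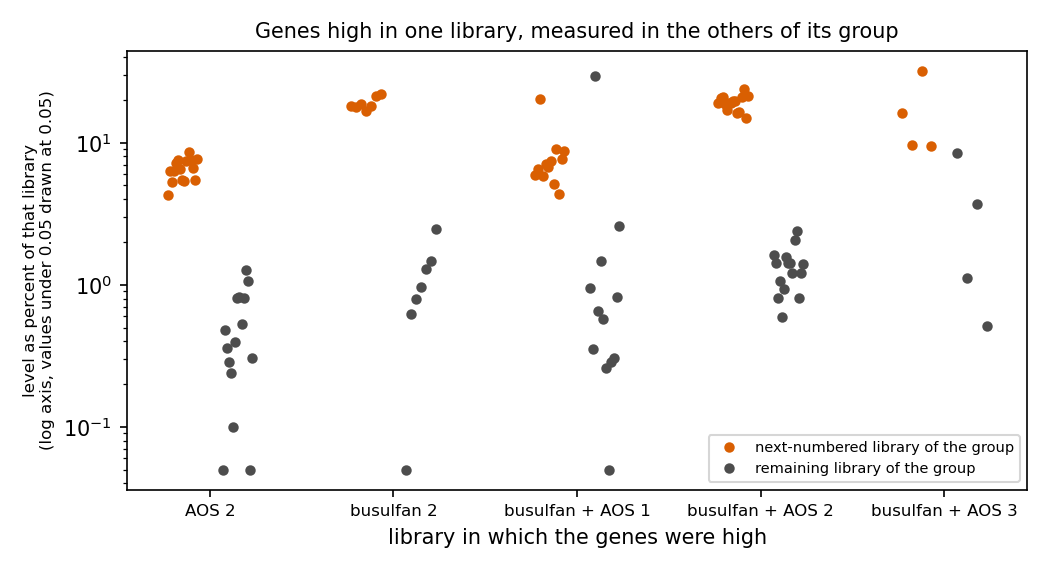
Level of genes high in 1 library as a percent of that level (log axis) in the next-numbered library of the group and in the remaining one, each point being 1 gene, for the 5 libraries with at least 4 such genes. The median in the next-numbered library was 6.52% for AOS 2, 18.2% for busulfan 2 and 19.1% for busulfan + AOS 2, and 0.397%, 0.966% and 1.39% in the remaining library.

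The effect of busulfan alone was asked by comparing busulfan with control hearts. The genes with the smallest p were targets of p53, the transcription factor activated by DNA damage. Eda2r (gene 245527, mm10 chromosome X, 97333837 to 97377234) encodes a receptor of the tumour necrosis factor receptor family. It was at 0.867 ± 0.388 FPKM in control and 3.28 ± 0.809 in busulfan hearts (SD, n = 3 each, log2 fold change 1.85 ± 0.24 SE). Zmat3, an RNA-binding protein (gene 22401, chromosome 3, 32334792 to 32365665), was at 1.23 ± 0.263 and 2.53 ± 0.302 FPKM (log2 fold change 0.96 ± 0.14). Neither passed over all genes in edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p of 0.146 and 0.175. Both passed in DESeq2 and with the level of atrial markers as a covariate, a setting chosen after seeing the data (adjusted p = 0.0149 for both), and Eda2r also with that of adipocyte markers and without control replicate 3. Over the alternative settings the adjusted p ranged from 1.97e-08 to 0.649 for Eda2r and from 1.78e-05 to 0.679 for Zmat3. As a list, the 20 p53 targets were higher after busulfan (camera adjusted p = 6.71e-05, and adjusted p = 0.0411 with an estimated correlation). Of these, 14 had a higher and 6 a lower mean, and 6 passed adjusted over the list alone, against 0 over all genes. Sesn2 and Polk were among them, with log2 fold changes of 0.98 and 0.52.

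Other genes near the top of the busulfan comparison, none past the threshold over all genes in the edgeR fit of the 12 libraries and each called by DESeq2, were Banp (log2 fold change 1.16), the small GTPase Rrad (-1.15), the cold-inducible RNA-binding protein Cirbp (-0.71) and the surfactant gene Sftpc (-5.68). Sftpc, Banp and Rrad also passed with the atrial covariate, and Sftpc with only the groups compared and in limma on log2 FPKM. Sftpc was at 10.7 ± 3.60 FPKM in control and 0.210 ± 0.147 in busulfan hearts (SD, n = 3 each). It is a marker of lung epithelium, and the 5 tested lung epithelium markers were all lower. With the preset correlation they had the smallest camera p of the 37 lists (camera adjusted p = 1.99e-09). With an estimated correlation their adjusted p was 0.0623, and the p53 targets had the smallest camera p. The airway gene Scgb1a1 was at 45.7 to 85.1 FPKM in controls and at 0.76 to 2.06 after busulfan. The cardiac stress list was lower (camera adjusted p = 0.000785), with 11 of 12 members lower; Nppb and Myh7, a natriuretic peptide and a fetal myosin, had log2 fold changes of -1.93 and -0.79. Its adjusted p was 0.307 with an estimated correlation. In all, 7 lists were higher and 6 lower, and the 12 lists other than the p53 targets had adjusted p of 0.0623 to 0.915 with an estimated correlation. Among them were the adipocyte markers, all 10 of which had a higher mean after busulfan. No gene passed over all 14687 in edgeR (0 called, 1558 at an unadjusted p under 0.05). DESeq2 called 52, limma on log2 FPKM 1 and limma-voom 0. The count was 4 without control replicate 3 and 2 without busulfan replicate 1. It was 125 with the atrial covariate, 115 higher and 10 lower, with the fat genes Adipoq and Plin1 among the higher ones, and 28 with the adipocyte covariate, 1 higher and 27 lower.

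**Figure D3:**
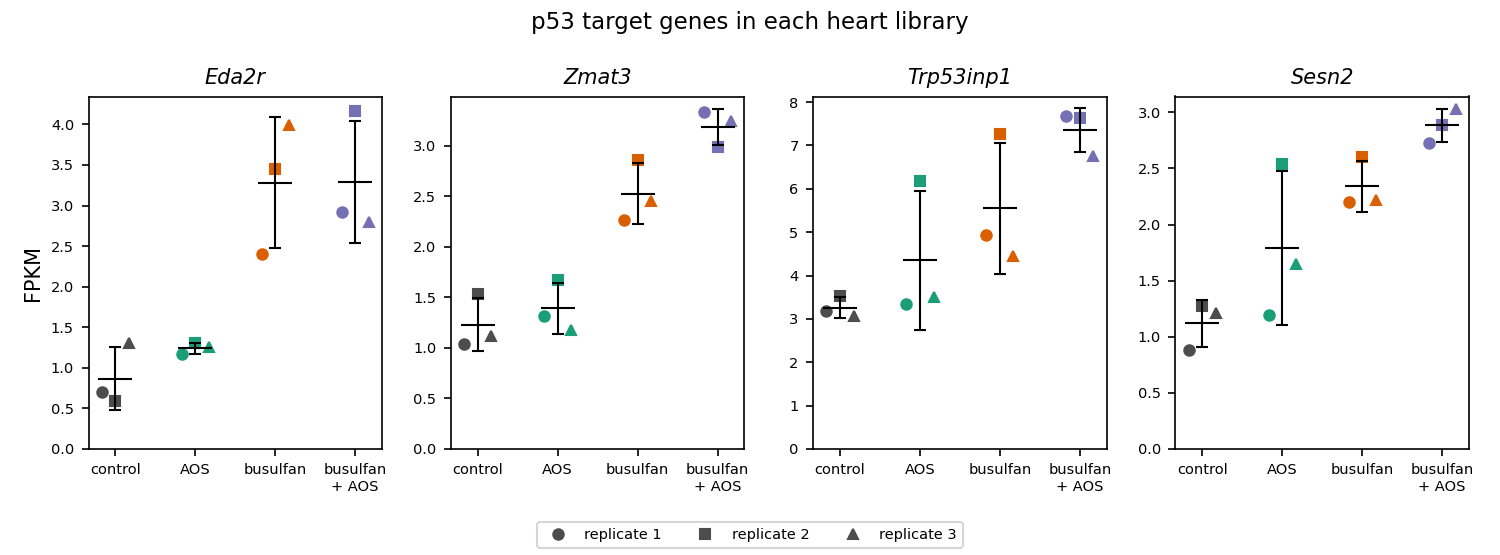
FPKM of the p53 targets Eda2r, Zmat3, Trp53inp1 and Sesn2 in the 12 libraries, with the mean and SD of each group of 3. Zmat3 averages 1.23 in control, 1.39 with AOS, 2.53 with busulfan and 3.19 with busulfan plus AOS.

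Whether AOS given after busulfan alters the heart transcriptome was asked by comparing busulfan plus AOS with busulfan. Genes that handle misfolded protein in the endoplasmic reticulum were among those with the smallest p, none past the threshold over all genes in edgeR. The unfolded protein response list was higher with AOS, with 13 of 14 members higher (camera adjusted p = 3.14e-08, and adjusted p = 0.283 with an estimated correlation). Of its members, 7 passed adjusted over the list alone and 0 over all genes. Sdf2l1, a chaperone cofactor, was at 5.53 ± 1.79 FPKM after busulfan and 14.6 ± 4.26 after busulfan plus AOS (SD, n = 3 each; log2 fold change 1.30). Pdia4 and Pdia6, which form disulfide bonds, had log2 fold changes of 0.90 and 0.54, and the stress transcription factor Ddit3 had 0.70. Creld2 (1.03), Syvn1 (0.70) and B4galt5 (0.81) were among the 10 genes with the smallest p. DESeq2 called these 3, Pdia6 and Ddit3, and each passed in only 1 of 26 alternative settings. With the atrial covariate, chosen after seeing the data, 0 genes passed in this comparison. The adjusted p in that edgeR fit was 0.859 for B4galt5 and 0.974 for Creld2, and higher for the others.

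Inflammatory cytokines were also higher as a list with AOS after busulfan, with 13 of 14 members higher (camera adjusted p = 3.80e-06, and adjusted p = 0.0435 with an estimated correlation). The monocyte chemoattractant Ccl2 was at 2.85 ± 0.467 FPKM and 8.28 ± 1.23 (SD, n = 3 each; log2 fold change 1.43), and Ccl6, Ccl7 and Icam1 had log2 fold changes of 1.28, 1.24 and 0.84. Of the list, 5 passed adjusted over the list alone and 0 over all genes. Interferon response genes were higher in 20 of 21 members, with a median log2 fold change of 1.47, and oxidative phosphorylation genes were lower in 23 of 24, with a median of -0.49. Both lists passed with the preset correlation and had adjusted p = 0.431 with an estimated correlation. Atrial markers moved with them, all 10 having a higher mean (median log2 fold change 2.68), as did macrophage and monocyte markers in 12 of 14 members (6 adjusted over the list alone and 0 over all genes) and neutrophil markers in 5 of 5, each with adjusted p = 0.431 with an estimated correlation. In all, 15 lists were higher and 6 lower, and 20 of the 21 lost their call with an estimated correlation. No gene passed in edgeR (0 called, 1494 at an unadjusted p under 0.05). DESeq2 called 53, limma-voom 0 and limma on log2 FPKM 0, and edgeR called 1 without busulfan replicate 1.

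AOS alone was compared with control. No named gene passed the threshold in edgeR; DESeq2 called Sftpc, Fxyd6 and Trim25 among them, and limma on log2 FPKM called Sftpc. The glutathione synthesis enzyme Gclc was at 4.53 ± 0.343 FPKM in control and 7.59 ± 2.10 in AOS hearts (SD, n = 3 each; log2 fold change 0.63, edgeR adjusted p = 0.642). Fxyd6, a regulator of the sodium pump, and Msrb1, a methionine sulfoxide reductase, had log2 fold changes of -0.71 and -0.65, and Sftpc had -4.35. The heat shock list was lower (camera adjusted p = 0.000128), with 12 of 13 members lower, among them Cryab at -0.66; B cell markers were higher in 6 of 6 members, with Jchain at 3.31. All 10 lists that passed, 5 higher and 5 lower, had adjusted p = 0.724 with an estimated correlation. The mean log2 CPM of the B cell markers was 3.15 in AOS replicate 2, the library with the most Scgb1a1 and Bmp10, 1.126 in AOS replicate 3 and -0.679 in AOS replicate 1, against -0.331 to 0.117 in controls. Adipocyte, atrial and mesothelium markers were at 5.856, 8.915 and 4.604 in AOS replicate 2, against at most 3.337, 7.115 and 3.194 in controls. In AOS replicate 1 they were at 2.055, 3.367 and 1.628. Trim25, also among the genes with the smallest p, was at 3.76 FPKM in AOS replicate 1 against 0.530 and 0.220 in the other AOS libraries. In edgeR 0 genes were called and 1017 had an unadjusted p under 0.05, against 8 called by DESeq2, 1 by limma on log2 FPKM and 0 by limma-voom. The count of 10 lists was 4 without AOS replicate 2, 17 without AOS replicate 1 and 16 without control replicate 2.

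Of the 4 pairs of groups, busulfan plus AOS against control had the most genes called. In edgeR 45 genes passed, 38 higher and 7 lower, and 4815 had an unadjusted p under 0.05. DESeq2 called 2391, 1254 higher and 1137 lower, limma with library weights 364, 238 higher and 126 lower, limma-voom 12 and limma on log2 FPKM 82. The unfolded protein response genes Sdf2l1 (log2 fold change 2.18 ± 0.29 SE, adjusted p = 0.02), Pdia4 (1.21 ± 0.19, 0.0440), Xbp1 (0.85 ± 0.14, 0.0462) and Calr (0.66 ± 0.11, 0.0480) rose, with 10 of 14 members past the threshold adjusted over the list alone and 4 over all genes. The list test gave a camera adjusted p of 3.47e-07, and adjusted p = 0.268 with an estimated correlation. Sdf2l1 (gene 64136, chromosome 16, 17130138 to 17132383) was at 2.82 ± 0.715 FPKM in control and 14.6 ± 4.26 after busulfan plus AOS (SD, n = 3 each). Among the p53 targets, Zmat3 and Eda2r rose by 1.19 and 1.78 on the log2 scale (edgeR adjusted p = 0.0134 and 0.02), and 8 of 20 members passed as higher and 2 as lower adjusted over the list alone. The list had a camera adjusted p of 0.00344, and adjusted p = 0.204 with an estimated correlation.

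Further genes that rose after busulfan plus AOS were the interferon-inducible Apol9a (log2 fold change 4.33), Wt1, a transcription factor of the epicardium (1.71), the receptor kinase Ret (1.55), Atp10a (1.85), Banp (1.62), Dok2 (1.36), Atad2 (1.36) and Cmklr1 (1.24). Genes that fell were the clock output gene Dbp (-1.38), Rrad (-1.27), Thnsl1 (-1.04), Ttc30b (-0.89), Cep70 (-0.67) and the lung epithelium marker Sftpc (-7.02). Each had an edgeR adjusted p under the threshold. Dbp was at 7.95 ± 1.13 FPKM in control and 3.46 ± 0.298 after busulfan plus AOS (SD, n = 3 each). Interferon response genes were higher in 21 of 21 members (median log2 fold change 2.35), 20 of them past the threshold adjusted over the list alone and 0 over all genes. Stat2 had a log2 fold change of 1.85. Extracellular matrix genes passed as higher in 12 of 20 members adjusted over the list alone, with Mmp2 at 0.98. Oxidative phosphorylation genes passed as lower in 22 of 24, with Cox6a2 at -0.96, and sarcomere genes in 4 of 17, with Myoz2 at -0.84. These lists had adjusted p = 0.505 with an estimated correlation, and all 18 lists that passed lost their call with it. All 10 adipocyte markers had a higher mean, and 7 passed adjusted over the list alone (adjusted p = 0.505 with an estimated correlation).

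The count of 45 depended on single libraries. It was 0 without control replicate 1 or replicate 1 of busulfan plus AOS, 1 without control replicate 2 and 21 without control replicate 3. It was 24, 2546 (1257 higher and 1289 lower) and 11 without AOS replicates 1, 2 and 3, 21, 13 and 9 without busulfan replicates 1, 2 and 3, and 8 and 4 without replicates 2 and 3 of busulfan plus AOS. All 45 genes kept their direction with the level of atrial or of adipocyte markers as a covariate, a setting chosen after seeing the data, and 1 and 0 of them then passed.

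**Figure D4:**
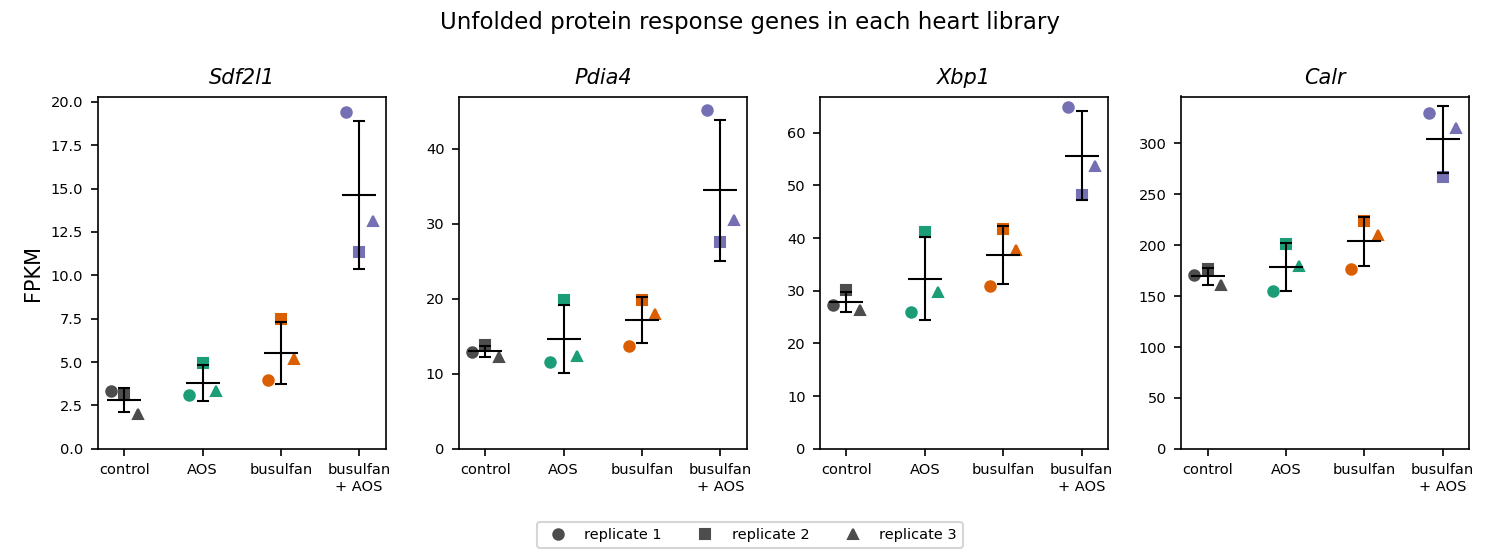
FPKM of the unfolded protein response genes Sdf2l1, Pdia4, Xbp1 and Calr in the 12 libraries, with the mean and SD of each group of 3. Sdf2l1 averages 2.82 in control, 3.8 with AOS, 5.53 with busulfan and 14.6 with busulfan plus AOS.

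With both busulfan groups set against both groups without it, 6 libraries against 6, 20 genes rose and 3 fell in edgeR. DESeq2 called 589, 423 higher and 166 lower, limma with library weights 818, 507 higher and 311 lower, and limma-voom 14, 13 higher and 1 lower. The adipocyte covariate gave 31, 4 higher and 27 lower, and the atrial covariate 331, 272 higher and 59 lower. The p53 targets Zmat3 (log2 fold change 1.05 ± 0.10 SE, adjusted p = 0.00656) and Eda2r (1.62 ± 0.17, 0.00806) had the smallest p. Banp (1.11), the chaperone Dnaja1 (1.38) and the collagen prolyl hydroxylase P4ha1 (0.98) also rose, and Cirbp fell by 0.66 on the log2 scale. The p53 list had a camera adjusted p of 5.67e-08, and adjusted p = 0.00821 with an estimated correlation. Of its 20 members, 10 passed as higher and 1 as lower adjusted over the list alone, against 2 over all genes. It was the only one of 16 lists past the threshold with the preset correlation that also passed with an estimated one. The count of 23 was 1, 2 and 15 without control replicates 1, 2 and 3, 4, 345 (235 higher and 110 lower) and 4 without AOS replicates 1, 2 and 3, 47, 4 and 3 without busulfan replicates 1, 2 and 3, and 5 and 9 without replicates 1 and 2 of busulfan plus AOS. With library totals in place of TMM scaling 5 genes passed, 100% of them higher, against 87% of the 23. An F test over the 4 groups called 11 genes in edgeR, 11 without busulfan replicate 1, 1 without control replicate 2 and 0 without any other single library.

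For the main effect of AOS, over both AOS groups against both others, 0 genes were called in edgeR and 2547 had an unadjusted p under 0.05. Mmrn2, an endothelial matrix protein, and Apol9a had the smallest p, with log2 fold changes of 0.39 and 2.89 (edgeR adjusted p = 0.286 for both). DESeq2 called 101 genes, limma-voom 0 and limma on log2 FPKM 0. Interferon response genes had a higher mean in 21 of 21 members and B cell markers in 6 of 6, and both lists had adjusted p = 0.494 with an estimated correlation. Atrial and adipocyte markers (10 of 10 each) and macrophage and monocyte markers (12 of 14) had a higher mean too, each with adjusted p = 0.494 with an estimated correlation. AOS replicate 2 stood apart from AOS replicate 1, with a mean log2 CPM of 5.066 against 2.764 for the interferon response and 3.15 against -0.679 for B cell markers.

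Whether the effect of AOS differed with busulfan was tested as an interaction. Unfolded protein response genes had a higher AOS effect after busulfan than without it in 13 of 14 members (camera adjusted p = 1.17e-12, and adjusted p = 0.0818 with an estimated correlation). Pdia6 and Ddit3 differed by 0.66 and 0.76 on the log2 scale, and 5 members passed adjusted over the list alone, against 0 over all genes. Heat shock genes went the same way in 13 of 13 members, with Hspb1 at 1.44 (adjusted p = 0.298 with an estimated correlation). In edgeR 0 genes were called and 432 had an unadjusted p under 0.05, with Ripor2 first at -2.17. DESeq2 called 5, limma-voom 0 and limma on log2 FPKM 0. Acadl, also among the genes with the smallest p, was at 75 FPKM in control replicate 2 and 45.4 in replicate 1 of busulfan plus AOS. It was at 0.270 or less in every AOS and busulfan library. In control replicates 1 and 3 it was at 0.52 and 6.22, and in replicates 2 and 3 of busulfan plus AOS at 1.8 and 0.12. Its log2 difference of 14.03 therefore rests on single libraries. Whether the values near 0 reflect expression or how its reads were counted was not tested.

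Across 14687 genes, which are not independent replicates, the AOS effect without busulfan and the AOS effect after busulfan had a Pearson correlation of 0.398 and a Spearman correlation of 0.505, with no library shared. Over 99 other regroupings of the 12 libraries the Pearson value had a median of -0.001 and a highest value of 0.577. It was 0.085 without AOS replicate 2, 0.260 without replicate 1 of busulfan plus AOS and 0.604 without control replicate 2. It was 0.010 with the atrial covariate, 0.025 with the adipocyte covariate and 0.074 without the 2 libraries highest in atrial and airway transcripts, settings chosen after seeing the data. The busulfan effect without and with AOS had a Pearson correlation of 0.252 and a Spearman correlation of 0.422, and the highest Pearson value among regroupings was 0.529. It was 0.097 without busulfan replicate 2, 0.167 without AOS replicate 3, 0.160 without replicate 1 of busulfan plus AOS and 0.396 without control replicate 2. No busulfan gene was called in edgeR, so the share of busulfan changes that AOS moved back toward control had no genes to be counted on. Of the p53 targets, Eda2r and Zmat3 had log2 fold changes of -0.06 and 0.23 between busulfan plus AOS and busulfan.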

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

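The tests of transcripts shared between libraries and of other tissue taken with the heart were chosen after the result was seen, as were the alternatives with a covariate, with 2 libraries left out and with shared transcripts subtracted, and the test of the smallest p of any list. The effect of AOS differed with and without busulfan for 9 gene lists by the interaction test with a preset correlation, and for 0 of 37 with an estimated one. The camera adjusted p was 1.17e-12 for the unfolded protein response, 1.38e-10 for heat shock, 1.09e-06 for immediate early genes, 1.19e-05 for cardiac stress genes and 0.000114 for inflammatory cytokines. It was 0.00121 for lung epithelium markers, 0.00258 for atrial markers, 0.00258 for fatty acid oxidation (the 1 list with a lower effect) and 0.00462 for the interferon response. The count of 9 was 23 without AOS replicate 2, 17 without replicate 2 of busulfan plus AOS, and 15 without control replicate 1 or busulfan replicate 2. Of 100 regroupings of the 12 libraries, 82 moved as many lists, so chance is not excluded for the count (9, highest other 23). With an estimated correlation some list had a p as small as that of the unfolded protein response in 13 of 100, so chance is not excluded for that list once its choice among the lists is allowed for (-log10 p of 2.355, highest other 3.437; 27 of 100 with the preset correlation).

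Many genes high in 1 library were present in the next-numbered library of its group at median shares of 6.52% (AOS 2), 18.2% (busulfan 2) and 19.1% (busulfan plus AOS 2). The next-numbered library held the higher median share for 9 of 10 source libraries, though 3 of these sources rest on 1 gene each. The count of 9 cannot tell material or reads passed between libraries from a separate share of other tissue in each heart. The direction of numbering was read from the same libraries that it uses. Shares of single genes do not decide between them. From AOS 2 to AOS 3 the atrial Bmp10 (7.15%) was near the airway genes Scgb1a1 (6.52%) and Bpifa1 (6.29%). Relative to replicate 1 of busulfan plus AOS, Bmp10 was at 20.2% in replicate 2 and 29.7% in replicate 3, against 6.57% and 0.355% for Bpifa1. Myl7 was at 1177 and 3121 FPKM in these replicates, so atrial tissue of each heart could add to Bmp10 there. This difference does not argue against passage. Acadl and Hbb-bs are not among the atrial, fat or airway markers. Their shares in the next-numbered library were 8.56% and 4.34% for Acadl and 9.19% and 9.52% for Hbb-bs. In the remaining library they were 0.307% to 3.59%. No biological explanation was tested.

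Atrial, fat, airway and liver transcripts varied between libraries of 1 group, Myl7 by as much as 489 times. Treatment is the same within a group, so it does not account for the spread among untreated controls, where the mean log2 level of the atrial list differed by 2.869. Within groups the 9 other members of the list rose and fell with Myl7 (correlations from 0.796 up, with a median of 0.890 against at most 0.802 in 10000 random gene sets), which is consistent with atrial tissue taken with the heart in varying amounts. Bmp10 was listed at 0 in control replicate 2, where Myl7 was at 3321 FPKM. A part of treatment in the differences between groups stays open, a permutation test of the level of the list over the 4 groups giving p = 0.251.

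The 45 genes that differed between busulfan plus AOS and control had a median absolute log2 fold change of 1.05 (median SE 0.17). With atrial marker level as a covariate 85.5% of it remained (bootstrap interval over genes 79.2 to 92.3, median SE 0.17) and 1 gene passed. That share is over the bound of 75% set for it. Genes pass the test by a small spread within groups, where the atrial level varied widely, so a high share was likely beforehand. Atrial content is therefore not excluded. Under library totals only, 115% of the median size remained. That setting moved the median log2 fold change of all genes from 0.04 to 0.23, and 38 of the 45 genes were higher. A larger size was therefore likely beforehand, so this share cannot tell whether scaling accounts for the differences. All 45 genes kept their direction there, and 39 of them passed. With adipocyte marker level as a covariate 76.8% remained (67.9 to 86.4) and 0 passed, the median falling to 0.81 and its SE rising to 0.22. The interval spans the bound of 75% set for it, but it resamples genes and does not measure the spread between libraries. Fat content cannot be told apart from treatment, because its level did not overlap between these groups. The mean log2 CPM of adipocyte markers was 0.539 to 3.337 in control and 5.702 to 7.062 in busulfan plus AOS libraries. The interval was added after the value was seen. The treatment itself remains open, and as many as 45 genes were called in 1 of 10 splits of the 6 libraries (highest other 0), too few splits for a share under 0.05.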

How the results depend on the processing

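The covariates, the fit without 2 libraries, the subtraction of shared transcripts, limma on log2 FPKM and the pair busulfan plus AOS against AOS were chosen after seeing the data. Of 72 results for named genes none reversed in any setting, though these genes were chosen for a small p or a large change in the same libraries. Of their 1839 values 280 lost their call and 50 gained one. Of 79 list results 26 reversed in 28 values, all under a covariate. A reversal of atrial markers with the atrial covariate, or of adipocyte markers with the adipocyte one, is circular, since the covariate is the mean of that list. Planned settings for a table without counts (pseudocounts of 0.1 and 0.5, quantile or median-of-ratios scaling, a variance trend) were not run, since counts were used, and DESeq2 gave no list test. Library totals only moved the median log2 fold change of all genes from 0.04 to 0.23 for busulfan plus AOS against control. With 3 libraries a group, simulated changes of 2-fold were recovered in 33.5% of genes between busulfan and control (14465 genes). Genes were drawn independently there, so that share need not hold for the real libraries. Where no reason is given, the cause was not tested.

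Counts of genes are for busulfan against control (0), busulfan plus AOS against busulfan (0), AOS against control (0), busulfan plus AOS against control (45), the interaction (0), the busulfan main effect (23), the AOS main effect (0) and any group (11), in edgeR. At an unadjusted p under 0.05 they were 1558, 1494, 1017, 4815, 432, 2522, 2547 and 2197. DESeq2 gave 52, 53, 8, 2391, 5, 589, 101 and 572, and 3 busulfan genes went the opposite way after AOS in place of 0. Both comparisons share the busulfan libraries, which favours opposite changes even without an AOS effect. No value from groups without an AOS effect is given beside that count, so it does not show a return toward control. For busulfan plus AOS against control, the busulfan main effect and any group, limma-voom gave 12, 14 and 0, an adjusted p under 0.1 gave 2334, 162 and 21, and subtraction of shared transcripts gave 7, 6 and 0. With it all 45 genes kept their direction and 103% of their median size (100 to 105), the median SE going from 0.17 to 0.19. Limma with library weights gave 364 and 818 for the first pair of these, library totals only gave 5 and 0 for the last pair, and the fit without 2 libraries gave 147, 90 and 0. With no filter the count for busulfan plus AOS against control was 16. With only the groups compared it was 422, and 3 for busulfan against control. Limma on log2 FPKM gave 1 for busulfan against control, 1 for AOS against control, 82 for busulfan plus AOS against control, 13 for the busulfan main effect and 2 for any group. The atrial covariate gave 125 for busulfan against control, 3 for AOS against control, 2 for busulfan plus AOS against control, 1 for the interaction, 331 and 1 for the main effects of busulfan and AOS and 51 for any group. The adipocyte covariate gave 28 for busulfan against control, 1 for busulfan plus AOS against busulfan and 0 for busulfan plus AOS against control. For busulfan plus AOS against AOS the count was 3 in edgeR (1384 at an unadjusted p under 0.05), 3 in limma-voom, 155 in DESeq2, 286 with library weights, 24 at an adjusted p under 0.1 and 1 with only the groups compared. It was 0 with library totals only, no filter, the replicate block, either covariate, 2 libraries left out, shared transcripts subtracted or limma on log2 FPKM.

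The replicate numbers did not pair the samples in all 4 groups. Correlations between libraries of the same number ranged from -0.452 to 0.554, with 6 of 18 above 0.1. Of 12 libraries, 6 correlated best with their own number. Among control, AOS and busulfan libraries, replicates 1 correlated at 0.230 to 0.491 and replicates 2 at 0.251 to 0.554. Replicates 3 were at -0.075 to 0.075. There, replicates 1 correlated with replicates 2 at -0.536 to -0.232. In these groups atrial and adipocyte markers were lowest in replicate 1 and highest in replicate 2. In busulfan plus AOS this order was inverted. Its same-number correlations with the other groups were -0.452 to 0.097. With the replicate number as a block, the count for busulfan plus AOS against control was 26, that for the busulfan main effect 5 and that for any group 0.

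With 1 library left out, the count ranged from 0 to 4 for busulfan against control, highest without control replicate 3. It ranged from 0 to 1 for busulfan plus AOS against busulfan, 0 to 0 for AOS against control, the interaction and the AOS main effect, and 0 to 2546 for busulfan plus AOS against control. The range was 1 to 345 for the busulfan main effect, both upper ends being without AOS replicate 2, 0 to 11 for any group, 0 to 1 for busulfan genes after AOS and 0 to 1 for busulfan plus AOS against AOS. A group left with 2 libraries shared the spread of the others.

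Lists moved numbered 13 for busulfan against control (10 to 15 with a library left out), 21 for busulfan plus AOS against busulfan (19 to 24), 10 for AOS against control (4 without AOS replicate 2 to 17 without AOS replicate 1) and 18 for busulfan plus AOS against control (16 to 20). They numbered 16 for the busulfan main effect (13 to 17), 9 for the interaction (7 to 23, highest without AOS replicate 2) and 21 for the AOS main effect (17 to 22). In that order an estimated correlation gave 1, 1, 0, 0, 1, 0 and 0, and fry gave 3, 2, 0, 3, 5, 0 and 0. For busulfan plus AOS against AOS 17 lists moved (15 to 21), 3 with an estimated correlation and 3 by fry. For AOS against control library weights gave 2 and the fit without 2 libraries 5. The atrial covariate gave 12 for busulfan plus AOS against busulfan and 7 for the AOS main effect. The adipocyte covariate gave 16 for the interaction and 11 for the AOS main effect, and the fit without 2 libraries gave 16 for the interaction. The correlation of AOS effects was 0.398 (0.085 without AOS replicate 2 to 0.604 without control replicate 2), 0.010 and 0.025 with the atrial and adipocyte covariates and 0.074 without 2 libraries. That of busulfan effects was 0.252 (0.097 without busulfan replicate 2 to 0.396 without control replicate 2), and 0.557 for genes above the median expression.

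The direction reversed with the atrial covariate between busulfan plus AOS and busulfan for sarcomere (camera adjusted p = 0.0956), calcium handling (0.347), cardiac ion channels (0.906), atrial markers (0.375), glycolysis (0.878), extracellular matrix (0.630), fibroblast (0.0502), skeletal muscle (0.615), mesothelium (0.0112) and Schwann cell markers (0.00409). It reversed between busulfan plus AOS and control (0.384) and between busulfan plus AOS and AOS (0.318) for atrial markers. With the adipocyte covariate it reversed between busulfan and control for sarcomere (0.980), oxidative phosphorylation (0.0794), glycolysis (0.313), extracellular matrix (0.588), adipocyte (0.418) and mesothelium markers (2.06e-05), and between AOS and control for adipocyte (0.966) and mesothelium markers (0.00697). Between busulfan plus AOS and control it reversed for calcium handling (0.372), atrial (3.16e-10), adipocyte (0.859) and mesothelium markers (0.164) and immediate early genes (0.230), and between busulfan plus AOS and AOS for calcium handling (0.914), atrial (9.07e-05) and adipocyte markers (0.876).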

Other observations

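Macrophage and monocyte markers were higher after busulfan plus AOS than in control in 12 of 14 members, 10 of them past the threshold adjusted over the list alone and 0 over all genes in edgeR. The complement gene C1qa was at 41.6 ± 7.17 FPKM in control and 99.1 ± 25.9 after both treatments (SD, n = 3 each; log2 fold change 1.08), and the mannose receptor Mrc1 and the chemokine receptor Ccr2 had log2 fold changes of 0.81 and 1.39. Mesothelium markers were higher in 6 of 6 members, 4 of them adjusted over the list alone and 1, Wt1, over all genes, with Upk3b at 2.66. All 10 adipocyte and all 10 atrial markers had a higher mean too, and the direction of the mesothelium list turned with the adipocyte covariate, chosen after seeing the data (camera adjusted p = 0.164). Glycolysis genes were lower in 17 of 18 members, 8 of them past the threshold adjusted over the list alone and 0 over all genes. Gapdh was at 112 ± 31.9 FPKM in control and 43.3 ± 11.8 after both treatments (SD, n = 3 each; log2 fold change -1.52). All 3 lists had adjusted p = 0.505 with an estimated correlation.

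Busulfan plus AOS against AOS, a pair added after seeing the data, had 3 genes called in edgeR, all higher and named after their values were seen: Zmat3 (log2 fold change 1.13), the tubulin Tubb2a (0.86) and Mtmr4 (0.79). The count was 1 without control replicate 2 and 0 without any other single library, and DESeq2 called 155, 117 higher and 38 lower. Unfolded protein response genes were higher in 13 of 14 members (10 adjusted over the list alone, 0 over all genes; adjusted p = 0.0203 with an estimated correlation). Inflammatory cytokines were higher in 11 of 14 (6 and 0; adjusted p = 0.0253 with an estimated correlation) and p53 targets in 16 of 20 (10 and 1; adjusted p = 0.0121 with an estimated correlation). Of 17 lists past the threshold with the preset correlation these 3 also passed with an estimated one. Markers of other cells ranged higher too, with overlap between the groups. The mean log2 CPM of macrophage and monocyte markers was 3.941 to 4.821 with AOS and 4.427 to 5.112 with busulfan plus AOS. It was 2.055 to 5.856 and 5.702 to 7.062 for adipocyte markers, and 1.628 to 4.604 and 3.973 to 5.435 for mesothelium markers.

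Over both busulfan groups against both others, heat shock genes were higher in 12 of 13 members. Adjusted over the list alone 9 passed as higher and 1 as lower, against 1 over all genes in edgeR. Hsph1 and Hsp90aa1, both chaperones, had log2 fold changes of 1.69 and 1.08, and the list had adjusted p = 0.382 with an estimated correlation. The median log2 fold change of the list was 0.164 for busulfan against control (0 members adjusted over the list alone; adjusted p = 0.915 with an estimated correlation) and 1.236 for busulfan plus AOS against AOS (10 of 13; adjusted p = 0.16 with an estimated correlation), and 12 of 13 members were lower with AOS alone (adjusted p = 0.724 with an estimated correlation). Hsph1 ranged from 23.88 to 49.42 FPKM in controls, from 25.09 to 29.11 with AOS, from 48.3 to 128 in the busulfan libraries and from 87.3 to 214 after busulfan plus AOS. Markers of other tissue moved in the same main effect. With the atrial covariate, chosen after seeing the data, 7 of 10 adipocyte and 4 of 6 mesothelium markers passed as higher over all genes. Of the heat shock genes 2 of 13 did.

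Other groupings of the libraries were tested for each count, with the predictions written before their results, except for the test of the smallest p of any list. For the busulfan main effect 2 of 100 regroupings gave 23 genes or more, and the highest other gave 122, several times the real count, while the remaining ones gave at most 1. That regrouping points to a structure of the samples other than the busulfan grouping. It is the AOS grouping with control replicate 2 and AOS replicate 1 exchanged, and the mean log2 CPM of the atrial markers was 6.355 to 8.915 in the 6 libraries on 1 side of it and 2.742 to 6.488 in the 6 on the other. By the share alone these 23 genes and the 11 genes of any group (1 of 100, highest other 1) were under the bound of 0.05 set for chance. Regrouping treats the libraries as exchangeable, but libraries of a group shared transcripts. The share therefore cannot tell treatment from what libraries of a group held in common. With shared transcripts subtracted 6 and 0 genes were called. For the p53 targets under the busulfan main effect some list had a p as small with an estimated correlation in 2 of 100 (-log10 p of 3.654, highest other 3.785). That share allows for the choice of list but rests on the same exchange of libraries. This version of the test was chosen after others were seen. With the preset correlation some list had a p as small in 77 of 100 (8.212, highest other 30.241), and that version does not exclude chance. Chance was not excluded for lists under the busulfan main effect (33 of 100; 16, highest other 26) or the AOS main effect (5 of 100; 21, highest other 24). Nor was it for the correlation of AOS effects (5 of 100; 0.398, highest other 0.577) or of busulfan effects (26 of 100; 0.252, highest other 0.529). In edgeR 0 genes were called for the AOS main effect (highest other 4) and for the interaction (highest other 1), so all 100 regroupings gave as many. At an unadjusted p under 0.05 these had 2547 and 432 genes, and DESeq2 called 101 and 5.

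The 10 splits of 6 libraries are too few for a share under 0.05. Busulfan against control had 13 lists and the highest other split 15 (3 of 10 as many), busulfan plus AOS against busulfan 21 and 19 (1 of 10), AOS against control 10 and 19 (9 of 10), busulfan plus AOS against control 18 and 19 (2 of 10) and busulfan plus AOS against AOS 17 and 18 (5 of 10). The last of these had 3 genes called and the highest other split 1. Gene counts of the first 3 of these were 0 in edgeR in all 10 splits, with 1558, 1494 and 1017 genes at an unadjusted p under 0.05 and 52, 53 and 8 called by DESeq2.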
